A study of Homo sapiens with 16 samples.

How the data were processed

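Primary monocytes isolated from the blood of healthy donors were profiled by RNA sequencing of polyA-selected RNA in 16 libraries, 4 in each of 4 groups, per the labels. The deposited table holds whole-number counts of reads per gene with 1 column per library, which the authors made from their reads. It names 58381 genes by versioned Ensembl ID. The submitters' processing notes name fastp 0.19.10, STAR 2.7.3a, SAMtools 1.9 and featureCounts 2.0.1 with genome build hg38, per the submitters' processing notes, with no role or order for each. The annotation release, the strand setting, the treatment of reads that map to several places and the vehicle given to cells without inhibitor are not given in the sources used here. Without the strand setting, reads of a gene and of an antisense gene that overlaps it cannot be told apart, and genes with near-identical copies have uncertain counts. The doses of CXCL4 (10 µg) and ORN8L (20 µg) have no volume in the labels.

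Symbols were found for 58261 of the 58381 IDs. Of the IDs, 56933 are identical, version included, to those of GENCODE release 29, from which chromosome, start and end were taken. Genes of the Y chromosome, XIST and TSIX, 565 in all, were left out before any test because the samples come from people, which left 57816. Total counts ran from 9294073 to 21022287 (median 16361917.5).

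Each library was placed in a group by its title. For 8 of the 16 libraries the treatment field names another group than the title, 2 libraries in each group of titles have both labels alike, and alternatives with the groups of the treatment field and with only the 8 libraries whose labels are alike were run. The groups, comparisons, tests, gene lists, rule for named genes and alternatives were fixed before the data were examined. Libraries with the same replicate number come from the same donor by the titles. The correlation of their deviations from the group means, across genes, was 0.256 to 0.655 (median 0.415, 24 of 24 pairs above 0.1), and in 24 of 24 pairs it was highest for the same number. The numbers were therefore taken to pair the libraries. The main fit, fixed before the data were examined, has no block and leaves donor differences in its spread. The fit with the replicate number as a block was an alternative. In the order of the report it called 9851, 4398, 4669 and 5615 genes, more than the main fit each time. Its values are given where it changed the call of a printed gene or list by edgeR or camera, or moved a printed number of genes or of list members by 1.5 times or more. No library was a copy of another: chi-square per degree of freedom between libraries of a group ran from 26.4 to 325, and the correlation of their log CPM from 0.925 to 0.985.

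Genes were kept by filterByExpr of edgeR, which left 13624. They were normalized by TMM and tested by edgeR's two-sided quasi-likelihood test with robust dispersion in 1 fit of all 16 libraries with 1 mean per group (12 residual degrees of freedom, 9 with the block, common biological coefficient of variation 0.289, 0.184 with the block). Adjusted p-values are those of Benjamini and Hochberg, and a gene is said to rise or fall where the adjusted p is under 0.05. Fold changes are on the log2 scale with their standard error, and levels are means of CPM (counts scaled to effective library size) with the SD over 4 libraries. Gene lists, 36 with 777 genes of which 775 were found, were tested by camera of limma with the preset inter-gene correlation 0.01 and again with an estimated correlation, adjusted over the 34 lists with at least 5 genes measured. The other 2, interferon genes and erythroid markers, had fewer genes measured and were not tested. A list is said to move where camera's adjusted p is under 0.05, which compares its genes with all others. Library composition was compared by exact two-sided permutation tests, and the overlap of changed genes by Fisher's exact test.

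The rule for named genes took, per comparison, the 5 most raised and 5 most lowered genes past the threshold with at least 5 CPM in the higher group and the same direction in all 4 same-numbered pairs, leaving out genes with no symbol, HLA genes and immunoglobulin or T cell receptor segments. It also took the 2 members of each list with the largest change among those past the threshold with at least 1 CPM, and 20 genes fixed by name. The genes printed are a selection from these that was chosen after their values were seen, and 1 gene of that selection is not reported here. Alternatives were RLE normalization, no filter, a filter of at least 1 CPM in 8 libraries, only the 2 groups compared, DESeq2, limma-voom, the block, fry in place of camera, and each library and each replicate number left out in turn. A fit without 2 libraries that stand apart from their groups was added after seeing the data. These 2 are of different donors. Leaving out 1 library, or these 2, breaks donor pairs, so the groups then differ in donors in a fit without the block.

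The pipeline was tested on simulated counts with 200 genes changed by known folds. For the comparisons in the order of the report, 75.8%, 72.7%, 84.8% and 74.2% of the genes changed 4-fold were recovered. Of those changed 2-fold it was 49.3%, 46.3%, 44.8% and 37.3%. Of those changed 1.5-fold it was 4.48%, 5.97%, 7.46% and 8.96%, so changes of this last size are mostly missed by the fit without the block. The simulated spread was that of this fit, and depth and number of donors were not varied. Of the calls in these simulations, 5 of 91, 6 of 89, 4 of 95 and 2 of 82 were false. The recovery that the test had to reach was first set above what it gave for 4-fold changes and was lowered after the values were seen. In the simulated lists the raised list was found and 0 of 20 unchanged lists were under an unadjusted p of 0.05. Genes were drawn independently there, so this does not test lists whose genes move together. The estimated correlation of the interferon-stimulated genes was 0.61 in the comparison of NSA with the stimulus alone. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.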

Results

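Gene expression was measured by polyA RNA sequencing in 16 libraries of primary blood monocytes from healthy donors. Monocytes are circulating myeloid cells that sense microbial and self nucleic acids. The cells were kept overnight with the growth factor M-CSF at 20 ng per ml, and the cultures of 3 groups were then stimulated for 6 h with CXCL4 (10 µg), a chemokine stored in platelets, together with ORN8L (20 µg), an RNA ligand of the endosomal receptor TLR8. Of these, 1 group was pretreated with NSA (given only as an abbreviation in the labels and taken here as necrosulfonamide, known as an inhibitor of the necroptosis effector MLKL) and 1 with NSA plus GSK872, an inhibitor of the kinase RIPK3. Each of the 4 groups (unstimulated, CXCL4+ORN8L, NSA+CXCL4+ORN8L and NSA+GSK872+CXCL4+ORN8L) held 4 replicates, numbered by donor. The title and the treatment field name different groups for 8 of the 16 libraries, and the groups follow the titles. Total counts per library ran from 9294073 to 21022287 (median 16361917.5), with 17830 to 20882 genes counted at least once. The series asks what part RIPK3 plays in the interferon response and the NLRP3 inflammasome of monocytes exposed to this stimulus.

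The 10 most counted genes took 7.58% ± 0.916 of the counts in unstimulated cells, 11.1% ± 4.80 with CXCL4+ORN8L, 15.5% ± 1.51 with NSA added and 13.9% ± 1.52 with both inhibitors (SD, n = 4). Mitochondrial transcripts made up 3.45% ± 0.949, 2.71% ± 0.705, 2.83% ± 0.399 and 3.27% ± 0.414 in the same order. A two-sided exact permutation test of both shares and of the number of genes with a count gave a lowest of 12 adjusted p of 0.51. As the smallest raw p that 4 against 4 libraries allow is 0.0286, a single difference could not pass after adjustment, so the test does not show that the groups were alike. That test leaves the same-numbered pairs aside. Within pairs the mitochondrial share was lower in 4 of 4 with the stimulus and the share of the 10 genes lower in 4 of 4 with GSK872 on top of NSA (exact paired p of 1 in 8 for both, the smallest that 4 pairs allow). CXCL4+ORN8L replicate 1 had the lowest depth (9294073 counts) and the largest share in 10 genes (18.1%). IFNL1, an interferon lambda gene, had 0 counts in all 16 libraries and was not tested; a count of 0 allows up to 3 counts over a group, for counting error only.

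The first comparison asked what CXCL4 and ORN8L did to monocytes. Of the inflammatory cytokine genes 25 of 25 rose (25 adjusted over the list alone), and of the chemokine genes 24 of 24 rose (24 adjusted over the list alone). IL12B, a subunit of interleukin 12, stood at 567 ± 464 CPM against 0.636 ± 0.416 (SD, n = 4). IL6 stood at 1279 ± 1438 CPM against 3.04 ± 1.58 (SD, n = 4). Without CXCL4+ORN8L replicate 1 the stimulated means of these 2 genes were 349.8 and 569 CPM. Of the type I interferon-stimulated genes, 42 of 43 rose (42 adjusted over the list alone), with a median log2 fold change of 3.59. Of the macrophage identity genes 4 of 21 rose and 13 fell (4 and 13 adjusted over the list alone). MERTK, a receptor for the uptake of dying cells, fell to 2.57 ± 1.04 CPM against 228 ± 52.0 (SD, n = 4). By edgeR's quasi-likelihood test 8804 of 13624 genes differed, 4396 higher and 4408 lower, and 5874 of them by at least 2-fold. TMM assumes that most genes do not change, and the RLE alternative assumes the same. The split into higher and lower genes depends on that assumption. TMM factors were 1.45 to 1.53 in unstimulated and 0.697 to 1.06 in stimulated libraries. A gene with the same share of all counts in both groups thus appears higher with the stimulus.

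TNF and IL1B, both early inflammatory cytokines, rose (log2 fold changes ± SE of 8.68 ± 1.01 and 8.94 ± 0.74; adjusted p = 2.4e-06 and 5.9e-08 by edgeR; higher in 4 of 4 same-numbered pairs). IL1RN, an antagonist of the interleukin 1 receptor, and INHBA, an activin subunit, rose as well (log2 7.73 ± 0.54 and 9.50 ± 0.94, adjusted p = 1.1e-08 and 4.3e-07 by edgeR). ACOD1, which makes itaconate, IDO1, which degrades tryptophan, and TNIP3, an inhibitor of NF-kB signalling, rose too (log2 10.31 ± 1.17, 9.93 ± 1.15 and 9.46 ± 0.67, adjusted p = 1.9e-06, 2.4e-06 and 1.4e-08 by edgeR). Of the NF-kB pathway and feedback genes, 26 of 27 rose (26 adjusted over the list alone). Of the cytokine signalling brakes, 15 of 20 rose and 3 fell (15 and 3 adjusted over the list alone), led by SOCS3 (log2 8.25 ± 0.53, adjusted p = 5.3e-09 by edgeR). Of the interferon-gamma-type genes, 21 of 25 rose and 2 fell (22 and 2 adjusted over the list alone). CXCL10 and CXCL11, chemokines that draw T cells, and LAMP3, a lysosomal protein of mature dendritic cells, were the interferon-stimulated genes named here with the largest changes (log2 7.35 ± 0.78, 8.49 ± 0.95 and 9.11 ± 0.60, adjusted p = 9.0e-07, 1.7e-06 and 8.1e-09 by edgeR). IFIT1, ISG15 and MX1, antiviral effectors, rose by less (log2 3.65 ± 0.42, 4.47 ± 0.42 and 4.37 ± 0.42, adjusted p = 1.9e-06, 2.4e-07 and 3.0e-07 by edgeR). IFNB1, which encodes interferon beta, had 3 counts over the 4 unstimulated libraries and 136 over the 4 stimulated ones (adjusted p = 0.00093 by edgeR). Their ratio was 72.0 per effective library size (95% exact interval 24.1 to 353, counting error only). It was 29.6 without CXCL4+ORN8L replicate 1, which held 86 of the 136 counts (9.56 to 148), and 153 without unstimulated replicate 4 (27.1 to 6102). Folds that moved by more than 1.5 times without 1 library were, on the log2 scale, TNF 7.23, IL6 7.53, IL1B 8.15, IL12B 9.06, INHBA 8.65 and IFNB1 4.65 without CXCL4+ORN8L replicate 1. Without unstimulated replicate 2 they were INHBA 10.20, ACOD1 11.62, IDO1 10.93, TNIP3 10.26 and LAMP3 10.35. Without CXCL4+ORN8L replicate 4 they were ACOD1 9.67 and CXCL10 6.75. Without unstimulated replicate 4 that of IFNB1 was 7.41.

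Among inflammasome and pyroptosis genes, 15 of 24 rose and 8 fell (15 and 9 adjusted over the list alone). NLRP3, the sensor, CASP1, the protease that matures interleukin 1 beta, and GSDMD, the pore former, rose (log2 2.65 ± 0.57, 1.42 ± 0.28 and 1.80 ± 0.18, adjusted p = 0.00078, 0.00040 and 5.9e-07 by edgeR). IL18 stood just past the threshold (log2 1.18 ± 0.50, adjusted p = 0.049 by edgeR). Of the necroptosis and cell death receptor genes, 15 of 27 rose and 4 fell (15 and 4 adjusted over the list alone). The antiapoptotic gene BCL2A1 rose and the initiator caspase CASP8 fell (log2 8.19 ± 0.48 and -1.05 ± 0.14, adjusted p = 1.9e-09 and 6.3e-06 by edgeR). RIPK3 and MLKL did not pass the test (log2 -0.16 ± 0.14 and 0.20 ± 0.22, adjusted p = 0.34 and 0.43 by edgeR). TLR8 itself and the kinase TBK1 rose (log2 3.03 ± 0.57 and 1.60 ± 0.11, adjusted p = 0.00024 and 7.2e-09 by edgeR). STING1, an adaptor for cytosolic DNA, fell (log2 -3.04 ± 0.35, adjusted p = 1.8e-06 by edgeR). IRF5, a transcription factor downstream of TLR8, was not called (log2 -0.33 ± 0.20, adjusted p = 0.15 by edgeR). The chemokine receptor CCR7 and the costimulatory ligand CD80 rose (log2 8.70 ± 0.97 and 6.29 ± 0.42, adjusted p = 1.5e-06 and 8.6e-09 by edgeR). The fractalkine receptor CX3CR1, the adenosine receptor ADORA3, the receptor GPR34 and the RANK gene TNFRSF11A fell (log2 -4.98 ± 0.61, -7.69 ± 0.25, -7.41 ± 0.32 and -7.25 ± 0.28, adjusted p = 4.0e-06, 2.1e-11, 1.2e-10 and 6.4e-11 by edgeR). Of the nuclear oxidative phosphorylation genes, 1 of 25 rose and 15 fell (1 and 15 adjusted over the list alone). NDUFB7, a complex I subunit, fell (log2 -1.63 ± 0.24, adjusted p = 2.2e-05 by edgeR).

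With camera's preset correlation 13 of 34 lists moved. Those that moved up were interferon-stimulated genes, interferon-gamma-type genes, cytokines, chemokines, NF-kB genes, necroptosis genes, immediate early genes, brakes, matrix genes, integrated stress response genes and unfolded protein response genes. In that order, camera's adjusted p-values were 2.7e-23, 1.8e-12, 3.4e-11, 9.4e-07, 1.0e-22, 0.00078, 0.0032, 3.1e-06, 0.034, 0.048 and 0.0028, and the same test gave adjusted p = 0.16, 0.16, 0.21, 0.15, 0.15, 0.15, 0.54, 0.15, 0.41, 0.41 and 0.47 with an estimated correlation. Those that moved down were macrophage identity genes and oxidative phosphorylation genes. Camera's adjusted p-values in that order were 0.034 and 0.034, and the same test gave adjusted p = 0.28 and 0.80 with an estimated correlation. With the replicate block the members that rose and that fell were 15 and 3 of the 26 immediate early genes, 16 and 6 of the 28 matrix genes and 16 and 1 of the 20 unfolded protein response genes. With it the LXR and lipid efflux list was added (adjusted p = 0.017 by camera, 0.23 with an estimated correlation). Of the matrix and tissue remodelling, immediate early, integrated stress response and unfolded protein response lists, 15 of 28, 16 of 26, 12 of 20 and 14 of 20 members rose (15, 16, 12 and 14 adjusted over the list alone) and 4, 2, 4 and 0 fell (4, 2, 5 and 0 adjusted over the list alone). Other splits of the 8 libraries moved up to 18 lists. The edgeR call of IL18 ended without any 1 of 7 of the 8 libraries, all but CXCL4+ORN8L replicate 2 (adjusted p up to 0.12). IRF5 passed edgeR's test without CXCL4+ORN8L replicate 4 (adjusted p = 0.049). The rise of NLRP3 was 1.55 on the log2 scale without CXCL4+ORN8L replicate 1.

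**Figure D1:**
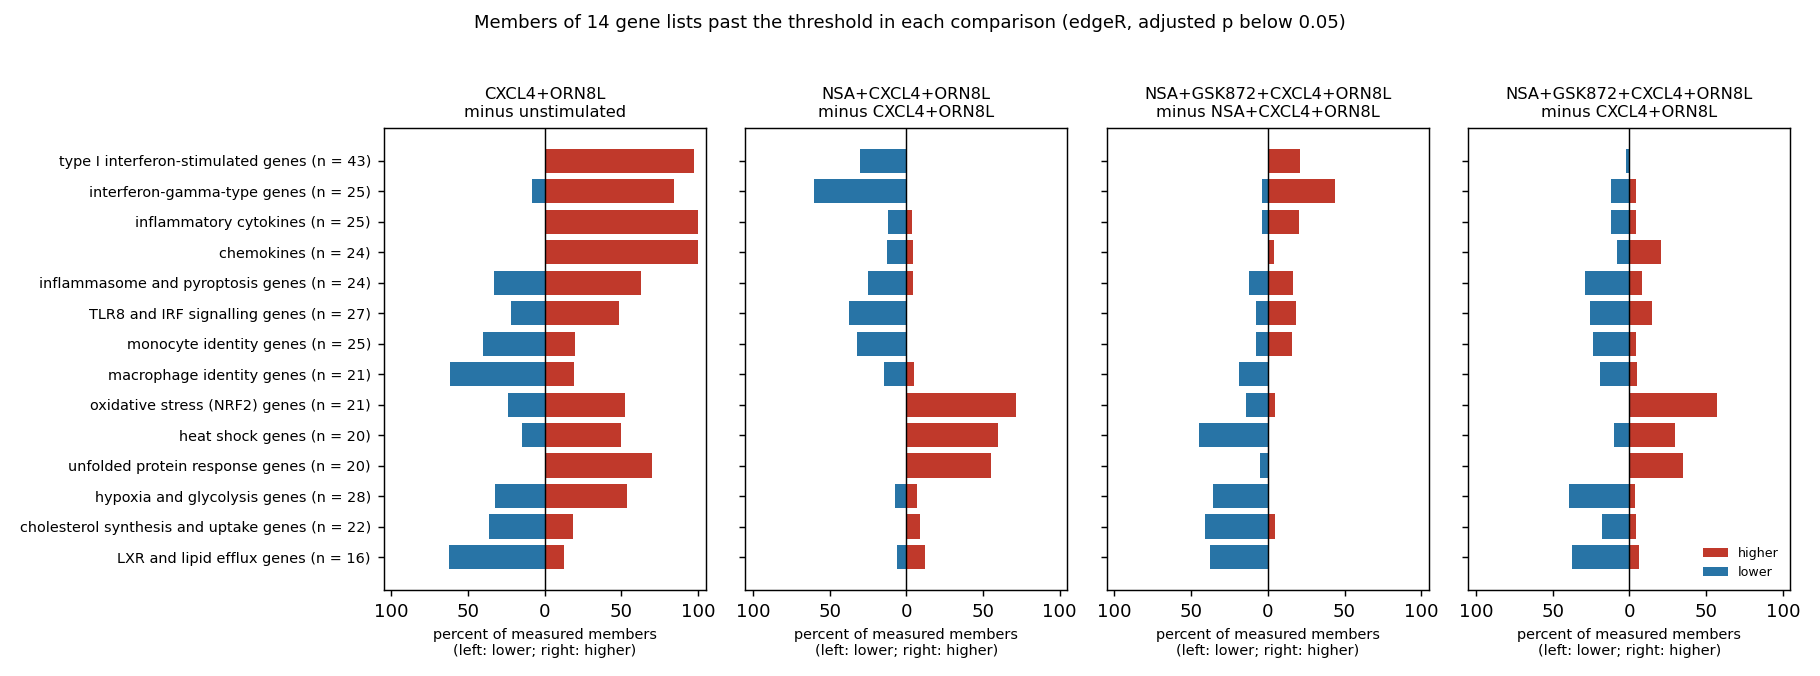
Percent of the measured members of 14 gene lists that passed edgeR's test in each of the 4 comparisons (horizontal axis, percent; bars to the right in red are members higher in the first group, to the left in blue lower; n is the number of members measured). With CXCL4+ORN8L, 25 of 25 inflammatory cytokine genes were higher; with NSA, 15 of 21 oxidative stress genes were higher and 15 of 25 interferon-gamma-type genes lower.

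The second comparison asked what NSA changed in stimulated cells. Of the oxidative stress genes driven by NRF2, 15 of 21 rose (17 adjusted over the list alone). HMOX1, which degrades heme, went to 5599 ± 2675 CPM against 371 ± 135 (SD, n = 4). GCLM, a subunit of the enzyme that starts glutathione synthesis, went to 612 ± 169 CPM against 76.6 ± 44.2 (SD, n = 4). Of the interferon-gamma-type genes 15 of 25 fell (19 adjusted over the list alone). Camera did not move the NK cell and neutrophil markers, though of the NK cell markers 2 of 8 fell (2 adjusted over the list alone; median log2 -0.67, camera adjusted p = 0.17, fry adjusted p = 0.024), and of the neutrophil markers 1 of 7 fell (1 adjusted over the list alone; median log2 -0.67, camera adjusted p = 0.15, fry adjusted p = 0.0091). CXCL10 stood at 59.8 ± 39.7 CPM against 642 ± 455 (SD, n = 4). TLR8 stood at 80.4 ± 74.2 CPM against 499 ± 167 (SD, n = 4), and its mean with NSA was 43.8 without NSA+CXCL4+ORN8L replicate 3. The mean of CXCL10 with the stimulus alone was 425 without CXCL4+ORN8L replicate 4. By edgeR's quasi-likelihood test 2571 of 13624 genes differed, 1164 higher and 1407 lower, 1181 of them by at least 2-fold. With the replicate block 4398 genes differed (2062 higher and 2336 lower), 2569 of them shared with the fit without it.

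HMOX1 and GCLM changed by 3.92 ± 0.52 and 3.01 ± 0.40 on the log2 scale (adjusted p = 0.00047 and 0.00048 by edgeR; higher in 4 of 4 pairs). Of the heat shock genes, 12 of 20 rose (16 adjusted over the list alone). The chaperone genes DNAJB4 and HSPH1 rose (log2 1.89 ± 0.33 and 1.16 ± 0.23, adjusted p = 0.0020 and 0.0040 by edgeR). Of the unfolded protein response genes, 11 of 20 rose (14 adjusted over the list alone). DNAJB9 and HERPUD1, both of the endoplasmic reticulum, rose (log2 1.16 ± 0.16 and 1.10 ± 0.24, adjusted p = 0.00061 and 0.0060 by edgeR). Of the amino acid and integrated stress response genes, 5 of 20 rose and 1 fell (5 and 1 adjusted over the list alone). SESN2, a stress-induced brake on growth signalling, rose (log2 1.29 ± 0.12, adjusted p = 0.00020 by edgeR). The gene raised most among those named here was HTRA3, a serine protease (log2 4.08 ± 0.73, adjusted p = 0.0023 by edgeR). Camera moved up NRF2 genes, heat shock genes, unfolded protein response genes and integrated stress response genes. In that order, camera's adjusted p-values were 1.3e-17, 4.7e-10, 5.0e-08 and 0.0069, and the same test gave adjusted p = 0.10, 0.23, 0.23 and 0.23 with an estimated correlation.

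Of the type I interferon-stimulated genes, 13 of 43 fell (26 adjusted over the list alone). CXCL10 and CXCL11 fell (log2 -3.43 ± 0.64 and -3.85 ± 0.73, adjusted p = 0.0028 and 0.0030 by edgeR). IFIT1, ISG15 and MX1 did not pass the test (log2 -0.999 ± 0.38, -0.93 ± 0.37 and -0.74 ± 0.37, adjusted p = 0.077, 0.090 and 0.17 by edgeR), nor did IFNB1 (log2 -2.78 ± 1.11, adjusted p = 0.093 by edgeR). Within same-numbered pairs IFIT1, ISG15, MX1 and IFNB1 were lower each time. IFNB1 levels were low, at 0.456 to 0.653 CPM with NSA. With the stimulus alone they were 13.3, 1.28, 0.937 and 0.632 CPM in replicates 1 to 4. The size of its fall thus rested mostly on CXCL4+ORN8L replicate 1. SERPING1, the C1 inhibitor, fell among the interferon-gamma-type genes (log2 -1.95 ± 0.41, adjusted p = 0.0057 by edgeR). Of the TLR8 and IRF signalling genes, 10 of 27 fell (1 rose and 10 fell adjusted over the list alone). TLR8, its relative TLR7 and IRF5 were lower (log2 -2.63 ± 0.56, -2.45 ± 0.41 and -1.24 ± 0.20, adjusted p = 0.0057, 0.0015 and 0.0014 by edgeR). TBK1 was not called (log2 0.15 ± 0.10, adjusted p = 0.36 by edgeR). ACOD1 fell most of the genes named here (log2 -4.47 ± 0.87, adjusted p = 0.0036 by edgeR). IL12B and the anti-inflammatory cytokine IL10 fell (log2 -2.75 ± 0.73 and -2.70 ± 0.56, adjusted p = 0.018 and 0.0050 by edgeR). TNF, IL6 and IL1B were not called (log2 0.09 ± 0.72, -0.04 ± 0.62 and 0.42 ± 0.52, adjusted p = 0.95, 0.98 and 0.62 by edgeR). No member of the NF-kB list of 27 passed by edgeR, 3 were lower at an unadjusted p under 0.05, and DESeq2 and limma-voom called 2 and 1 of them lower. In the fit with the replicate block 3 of its members rose and 4 fell. Of the monocyte identity genes, 8 of 25 fell (8 adjusted over the list alone), and of the dendritic cell markers 1 of 11 rose and 5 fell (1 and 5 adjusted over the list alone). VCAN, a matrix proteoglycan made by monocytes, MAF, a macrophage transcription factor, and CD80 were lower (log2 -2.50 ± 0.43, -3.30 ± 0.71 and -1.78 ± 0.33, adjusted p = 0.0019, 0.0063 and 0.0028 by edgeR). Folds of genes named here and past the threshold that moved by more than 1.5 times without 1 library follow, on the log2 scale. They were CXCL10 -2.83 and ACOD1 -3.83 without CXCL4+ORN8L replicate 4. Without NSA+CXCL4+ORN8L replicate 3 they were CXCL10 -4.03, CXCL11 -4.58, ACOD1 -5.58, IL12B -3.43, IL10 -3.55, TLR8 -3.54 and MAF -3.97. That of IL12B was -2.07 without CXCL4+ORN8L replicate 1. That of HTRA3 was 4.72 without CXCL4+ORN8L replicate 2. Without NSA+CXCL4+ORN8L replicate 2 that of HTRA3 was 3.48.

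In the inflammasome and pyroptosis list, 1 of 24 rose and 6 fell (1 and 6 adjusted over the list alone), and camera gave an adjusted p of 0.20. GSDMD and CASP5, an inflammatory caspase, fell (log2 -1.18 ± 0.18 and -2.06 ± 0.43, adjusted p = 0.0011 and 0.0055 by edgeR). NLRP3, CASP1 and IL18 were not called (log2 0.37 ± 0.54, -0.37 ± 0.28 and 0.17 ± 0.49, adjusted p = 0.68, 0.38 and 0.85 by edgeR). Of the necroptosis and cell death receptor genes, 1 of 27 rose and 5 fell (2 and 6 adjusted over the list alone), with a camera adjusted p of 0.057. RIPK3 fell from 12.7 ± 1.70 to 6.603 ± 0.675 CPM (SD, n = 4; log2 -0.94 ± 0.15, adjusted p = 0.0011 by edgeR). The death ligand TNFSF10 and the adaptor TRADD fell (log2 -1.67 ± 0.43 and -1.35 ± 0.25, adjusted p = 0.016 and 0.0025 by edgeR). MLKL was not called without the block (log2 0.61 ± 0.22, adjusted p = 0.063 by edgeR) and passed with it (adjusted p = 0.0095). CASP8 was not called (log2 -0.33 ± 0.14, adjusted p = 0.11 by edgeR).

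Camera moved down interferon-stimulated genes, interferon-gamma-type genes, TLR8 and IRF genes and monocyte identity genes. Camera's adjusted p-values in that order were 2.8e-09, 9.8e-11, 0.0069 and 0.0027, and the same test gave adjusted p = 0.42, 0.23, 0.23 and 0.26 with an estimated correlation. It also moved down metallothioneins, dendritic cell markers, antigen presentation genes and brakes. In that order, camera's adjusted p-values were 0.0029, 0.032, 0.028 and 0.043, and the same test gave adjusted p = 0.36, 0.23, 0.57 and 0.44 with an estimated correlation. Of these lists 4 of 11, 5 of 11, 4 of 20 and 6 of 20 members fell (5, 5, 5 and 8 adjusted over the list alone), and 0, 1, 0 and 1 rose (0, 1, 0 and 1 adjusted over the list alone). With the replicate block the members that rose and that fell were 0 and 20 of the 43 interferon-stimulated genes, 2 and 7 of the 24 inflammasome genes, 3 and 9 of the 27 necroptosis genes, 4 and 10 of the 27 TLR8 and IRF genes, 7 and 2 of the 20 integrated stress response genes, 0 and 9 of the 11 metallothioneins, 0 and 6 of the 20 antigen presentation genes, 0 and 12 of the 25 monocyte identity genes and 0 and 3 of the 8 NK cell markers. Metallothionein genes are near-identical copies, so their counts are uncertain. Other splits of the 8 libraries moved up to 17 lists, and 1 of them changed 2668 genes. Another, which sets donors 1 and 2 against donors 3 and 4 with both treatments on each side, changed 991. The edgeR count was 1516 without CXCL4+ORN8L replicate 4 and 1614, 1649 and 1655 without NSA+CXCL4+ORN8L replicates 1, 2 and 4. With all libraries of replicate 2 or of replicate 4 left out it was 765 and 515. It was 1111 with only the 8 libraries compared, 293 with only the libraries whose labels name 1 group. It was 4070 without CXCL4+ORN8L replicate 1 and NSA+CXCL4+ORN8L replicate 3, a choice made after seeing the data. As these are of different donors, the groups then differed in donors too, and that count does not separate NSA from donor. Single libraries decided some gene calls by edgeR: IL12B ended without NSA+CXCL4+ORN8L replicate 4 (adjusted p = 0.054) and TNFSF10 without CXCL4+ORN8L replicate 4 (0.058). NLRP3 and CASP8 passed without CXCL4+ORN8L replicate 1 (log2 1.44 and -0.47, edgeR adjusted p = 0.014 and 0.0091). That fit keeps NSA+CXCL4+ORN8L replicate 1 of the same donor. Within pairs NLRP3 was lower with NSA in replicate 1 (495 against 731 CPM) and higher in replicates 2, 3 and 4. MLKL passed without CXCL4+ORN8L replicate 2 or NSA+CXCL4+ORN8L replicate 1 (edgeR adjusted p = 0.030 and 0.043). IFIT1 and ISG15 passed without NSA+CXCL4+ORN8L replicate 3 (edgeR adjusted p = 0.049 and 0.0498).

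The third comparison, of NSA plus GSK872 against NSA alone in stimulated cells, is the design's contrast for RIPK3 inhibition, and GSK872 was always given with NSA. Of the type I interferon-stimulated genes 9 of 43 rose (12 adjusted over the list alone) with GSK872, and of the interferon-gamma-type genes 11 of 25 rose and 1 fell (14 and 1 adjusted over the list alone). Of the NK cell markers 3 of 8 rose (3 adjusted over the list alone; median log2 0.57, camera adjusted p = 0.23, fry adjusted p = 0.053), and of the platelet markers 2 of 7 fell (2 adjusted over the list alone; camera adjusted p = 0.23). Of the nuclear-retained transcripts 1 of 8 rose and 2 fell (1 and 4 adjusted over the list alone, 1 and 4 with the block; median log2 -0.75, camera adjusted p = 0.23), and of the ribosomal protein genes 2 of 33 fell (2 adjusted over the list alone, 7 with the block; median log2 -0.20, camera adjusted p = 0.051, fry adjusted p = 0.33). CXCL10 stood at 289 ± 241 CPM against 59.8 ± 39.7 (SD, n = 4). IL12B stood at 955 ± 811 CPM against 84.4 ± 66.7 (SD, n = 4). Without replicate 3 of NSA+GSK872+CXCL4+ORN8L the means of these 2 genes with both inhibitors were 171 and 573, and without that of NSA+CXCL4+ORN8L the mean of IL12B with NSA was 54.1. CASP1 was lower, at 46.2 ± 10.4 CPM against 118 ± 49.8 (SD, n = 4). P2RX7, the ATP-gated channel upstream of NLRP3, was lower, at 306 ± 155 CPM against 904 ± 289 (SD, n = 4). By edgeR's quasi-likelihood test 2547 of 13624 genes differed, 1199 higher and 1348 lower, 1061 of them by at least 2-fold. With the replicate block 4669 genes differed (2354 higher and 2315 lower), including all 2547 of the fit without it.

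IL12B, CXCL10 and GBP4, a guanylate-binding protein induced by interferon gamma, rose by 3.50 ± 0.75, 2.27 ± 0.61 and 1.72 ± 0.39 on the log2 scale (adjusted p = 0.0057, 0.019 and 0.0074 by edgeR; higher in 4 of 4 pairs). The death ligand TNFSF10, the costimulatory ligand CD86, the transcription factor CEBPD, the hyaluronan synthase HAS1 and TBK1 rose (log2 1.88 ± 0.44, 1.44 ± 0.21, 2.21 ± 0.45, 3.34 ± 0.54 and 0.41 ± 0.10, adjusted p = 0.0088, 0.00053, 0.0042, 0.0010 and 0.014 by edgeR). IFIT1, ISG15, MX1 and IFNB1 were not called (log2 0.85 ± 0.38, 0.84 ± 0.37, 0.36 ± 0.37 and 0.95 ± 1.12, adjusted p = 0.13, 0.12, 0.52 and 0.59 by edgeR). Within same-numbered pairs IFIT1, ISG15 and MX1 were higher each time, while IFNB1 went both ways. IL6 lay just short of the threshold (log2 1.85 ± 0.64, adjusted p = 0.055 by edgeR) and passed with the replicate block (adjusted p = 0.0098). So did TLR8 (log2 1.35 ± 0.54, adjusted p = 0.090 by edgeR, with the block adjusted p = 0.013). TNF, IL1B and IRF5 were not called (log2 -0.97 ± 0.73, 0.31 ± 0.52 and -0.24 ± 0.20, adjusted p = 0.37, 0.72 and 0.41 by edgeR). Within same-numbered pairs TNF was lower and IL1B higher each time, while IRF5 went both ways. Of the inflammatory cytokines, 5 of 25 rose and 1 fell (7 and 1 adjusted over the list alone). The member that fell was TNFSF15, a TNF-family cytokine (log2 -3.86 ± 0.80, adjusted p = 0.0049 by edgeR).

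Among the inflammasome and pyroptosis genes, 4 of 24 rose and 3 fell (4 and 3 adjusted over the list alone), and camera gave an adjusted p of 0.68. CASP1 and P2RX7 fell and GSDMD rose (log2 -1.35 ± 0.28, -1.56 ± 0.43 and 0.64 ± 0.18, adjusted p = 0.0049, 0.020 and 0.023 by edgeR). NLRP3 and IL18 were not called (log2 -0.10 ± 0.54 and 0.24 ± 0.49, adjusted p = 0.92 and 0.77 by edgeR). In the necroptosis and cell death receptor list, 5 of 27 rose and 2 fell (5 and 2 adjusted over the list alone). RIPK3, the target of GSK872, MLKL and CASP8 were not called (log2 0.18 ± 0.15, 0.15 ± 0.22 and -0.06 ± 0.14, adjusted p = 0.40, 0.67 and 0.79 by edgeR). The kinase IRAK1, which relays TLR signals, fell (log2 -1.64 ± 0.22, adjusted p = 0.00029 by edgeR). Of the cholesterol synthesis and uptake genes, 1 of 22 rose and 9 fell (1 and 11 adjusted over the list alone). The sterol enzymes SQLE and MSMO1 fell (log2 -2.06 ± 0.43 and -1.90 ± 0.36, adjusted p = 0.0053 and 0.0024 by edgeR). Of the LXR and lipid efflux genes, 6 of 16 fell (1 rose and 6 fell adjusted over the list alone). The lipid regulator PPARG fell (log2 -2.97 ± 0.22, adjusted p = 6.3e-06 by edgeR). Of the heat shock genes, 9 of 20 fell (10 adjusted over the list alone). HSPB1 and HSP90AB1 fell (log2 -1.19 ± 0.23 and -1.10 ± 0.24, adjusted p = 0.0032 and 0.0061 by edgeR). Of the hypoxia and glycolysis genes, 10 of 28 fell (2 rose and 15 fell adjusted over the list alone). The glucose transporter SLC2A1 fell (log2 -1.58 ± 0.23, adjusted p = 0.00041 by edgeR). Of the NRF2 genes, 1 of 21 rose and 3 fell (1 and 6 adjusted over the list alone). HMOX1 and the heme transporter SLC48A1 fell (log2 -1.83 ± 0.47 and -1.23 ± 0.29, adjusted p = 0.016 and 0.010 by edgeR).

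The protease CTSB, the inhibitory receptor HAVCR2, the ERK phosphatase DUSP6 and ANKRD22 fell (log2 -1.32 ± 0.15, -2.77 ± 0.32, -2.43 ± 0.61 and -2.46 ± 0.63, adjusted p = 0.00013, 0.00013, 0.014 and 0.015 by edgeR). The genes lowered most of those named here were TM4SF19, SPINK1, a trypsin inhibitor, and SPRY2, a brake on growth factor signalling (log2 -5.48 ± 0.89, -4.74 ± 0.91 and -4.59 ± 0.83, adjusted p = 0.0010, 0.0030 and 0.0021 by edgeR). Reads of TM4SF19 cannot be told from those of its antisense neighbour TM4SF19-AS1, as the strand setting of the counting is not given in the sources used here. Camera moved up interferon-stimulated genes and interferon-gamma-type genes. Camera's adjusted p-values in that order were 5.1e-05 and 5.1e-05, and the same test gave adjusted p = 0.65 and 0.65 with an estimated correlation. It moved down cholesterol genes, LXR genes, heat shock genes, hypoxia genes and NRF2 genes. In that order, camera's adjusted p-values were 0.00020, 0.0022, 0.00020, 0.00020 and 0.027, and the same test gave adjusted p = 0.65, 0.28, 0.65, 0.28 and 0.65 with an estimated correlation. The members that rose and that fell with the replicate block were 14 and 1 of the 43 interferon-stimulated genes, 17 and 1 of the 25 interferon-gamma-type genes, 10 and 3 of the 25 cytokines, 10 and 3 of the 27 necroptosis genes, 1 and 9 of the 16 LXR genes, 2 and 15 of the 28 hypoxia genes and 1 and 9 of the 21 NRF2 genes. Metallothioneins, whose near-identical copies make their counts uncertain, moved up with the replicate block alone (adjusted p = 0.021 by camera, 0.70 with an estimated correlation). Other splits of the 8 libraries moved up to 16 lists. The edgeR count was 1301 without NSA+CXCL4+ORN8L replicate 1, 1492 without NSA+GSK872+CXCL4+ORN8L replicate 3 and 1664 with no filter on low counts. It was 487, of which 23.8% were higher against 47.1%, with only the libraries whose labels name 1 group. By edgeR, TBK1 ended without NSA+CXCL4+ORN8L replicate 1 (adjusted p = 0.055). The calls of CXCL10, GSDMD and P2RX7 ended without that library, NSA+CXCL4+ORN8L replicate 2 or NSA+GSK872+CXCL4+ORN8L replicate 3 (edgeR adjusted p up to 0.087, 0.079 and 0.074). P2RX7 ended also without NSA+GSK872+CXCL4+ORN8L replicate 4 (0.063). IL6 passed without NSA+GSK872+CXCL4+ORN8L replicate 2 (log2 2.10, edgeR adjusted p = 0.045). TLR8 passed without NSA+CXCL4+ORN8L replicate 3 (log2 2.23, edgeR adjusted p = 0.0055). The fall of ANKRD22 was -1.53 on the log2 scale without NSA+CXCL4+ORN8L replicate 3. Other folds of genes named here and past the threshold that moved by more than 1.5 times without 1 library follow, on the log2 scale. They were IL12B 4.16, HAS1 4.26 and CXCL10 2.86 without NSA+CXCL4+ORN8L replicate 3. Without NSA+GSK872+CXCL4+ORN8L replicate 3 they were IL12B 2.77, CXCL10 1.52 and ANKRD22 -3.09. Without NSA+GSK872+CXCL4+ORN8L replicate 1 they were TM4SF19 -6.28, SPRY2 -5.31 and TNFSF15 -4.59. Without NSA+GSK872+CXCL4+ORN8L replicate 2 that of DUSP6 was -3.18.

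**Figure D2:**
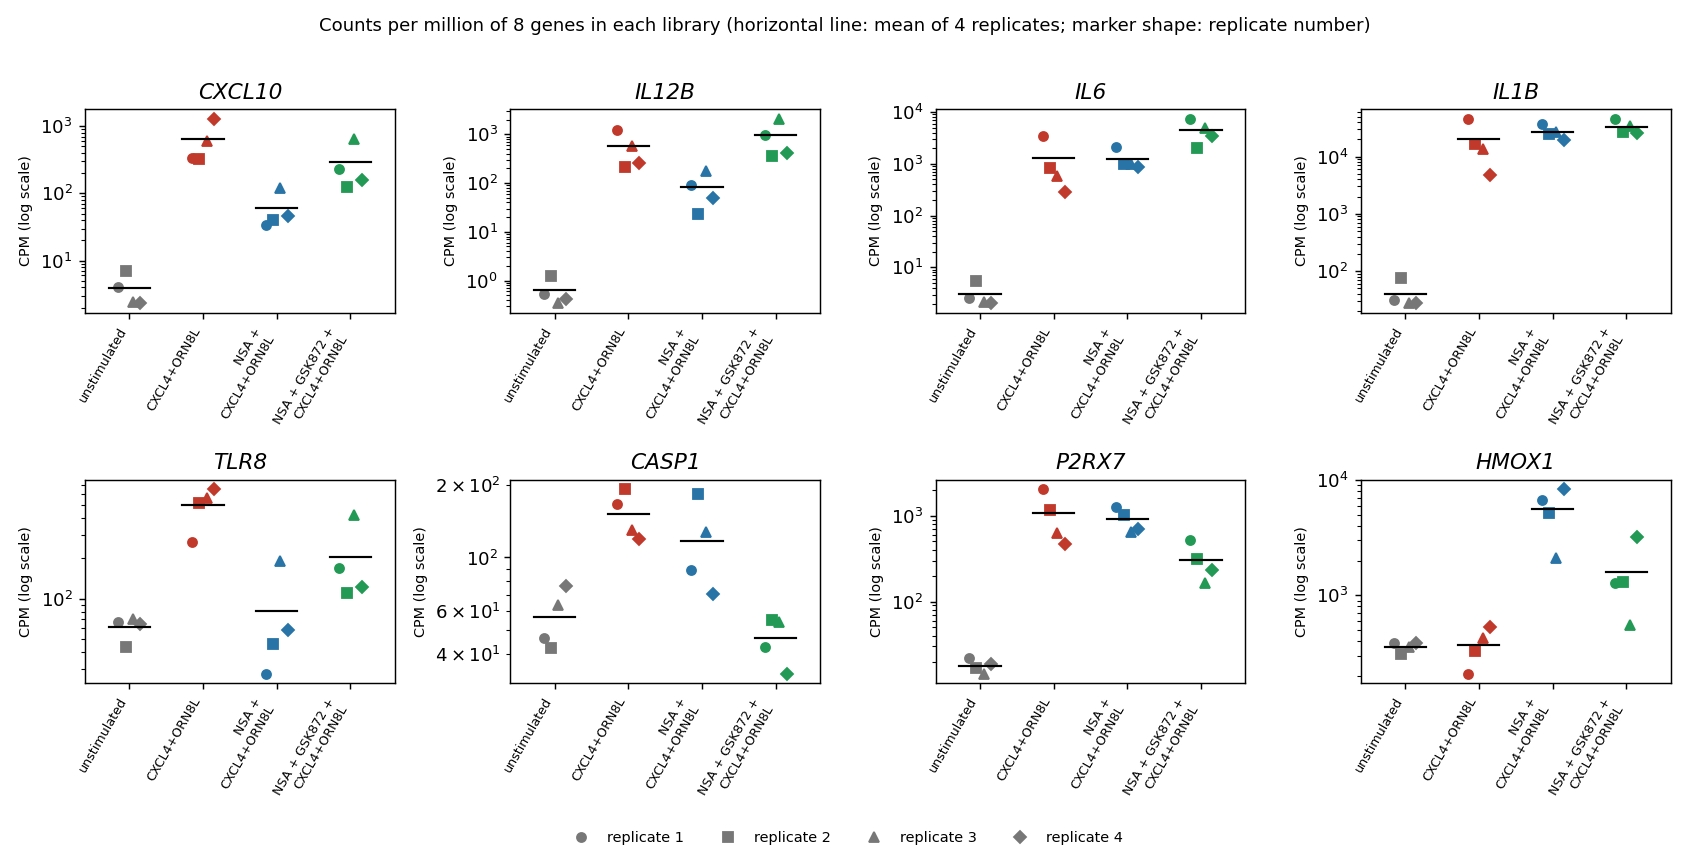
Levels of 8 genes in CPM in each of the 16 libraries (vertical log axis, CPM; groups on the horizontal axis; 1 point per library, marker shape by replicate number, horizontal line the mean of 4). CASP1 lay between 33.0 and 54.8 CPM with both inhibitors and between 70.9 and 183 with NSA, and HMOX1 between 2099.8 and 8379 with NSA and between 209 and 526 with the stimulus alone.

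The fourth comparison set both inhibitors together against the stimulus alone. CASP1 was lower with both, at 46.2 ± 10.4 CPM against 152 ± 33.6 (SD, n = 4). IRF5 was lower too, at 46.1 ± 13.8 CPM against 128 ± 25.5 (SD, n = 4). HMOX1 stood at 1579 ± 1122 CPM against 371 ± 135 (SD, n = 4), above the stimulus alone, and at 1045 without NSA+GSK872+CXCL4+ORN8L replicate 4. Of the NRF2 genes 12 of 21 rose (14 adjusted over the list alone). EREG, a ligand of the EGF receptor, was higher at 1045 ± 83.7 CPM against 167 ± 122 (SD, n = 4). CXCL10, IL12B, IFIT1, ISG15 and MX1 were not called (log2 -1.15 ± 0.59, 0.75 ± 0.68, -0.15 ± 0.37, -0.09 ± 0.36 and -0.38 ± 0.37, adjusted p = 0.16, 0.44, 0.80, 0.89 and 0.47 by edgeR). By edgeR's quasi-likelihood test 3807 of 13624 genes differed, 1770 higher and 2037 lower, 1713 of them by at least 2-fold.

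CASP1 and IRF5 fell (log2 -1.72 ± 0.28 and -1.48 ± 0.20, adjusted p = 0.00047 and 9.9e-05 by edgeR) and TBK1 rose (log2 0.55 ± 0.10, adjusted p = 0.0012 by edgeR), each in 4 of 4 pairs. Of the inflammasome and pyroptosis genes, 2 of 24 rose and 7 fell (3 and 7 adjusted over the list alone). P2RX7 and NAIP, whose near-identical copies make its counts uncertain, fell (log2 -1.81 ± 0.43 and -2.56 ± 0.58, adjusted p = 0.0059 and 0.0048 by edgeR). GSDMD was lower (log2 -0.54 ± 0.18, adjusted p = 0.036 by edgeR). NLRP3 and IL1B were not called (log2 0.27 ± 0.54 and 0.73 ± 0.52, adjusted p = 0.75 and 0.32 by edgeR). RIPK3 fell and MLKL rose (log2 -0.75 ± 0.14 and 0.76 ± 0.22, adjusted p = 0.0014 and 0.018 by edgeR). Of the TLR8 and IRF signalling genes, 4 of 27 rose and 7 fell (4 and 8 adjusted over the list alone). TLR7 and STING1 were lower (log2 -1.88 ± 0.39 and -1.79 ± 0.36, adjusted p = 0.0024 and 0.0021 by edgeR). TLR8 was not called without the block (log2 -1.29 ± 0.53, adjusted p = 0.084 by edgeR) but passed with it (adjusted p = 0.011). IL6 and the neutrophil chemokine CXCL5 rose (log2 1.81 ± 0.64 and 2.62 ± 0.73, adjusted p = 0.046 and 0.015 by edgeR). TNFSF15 fell (log2 -3.67 ± 0.80, adjusted p = 0.0034 by edgeR) and TNF was not called (log2 -0.89 ± 0.73, adjusted p = 0.39 by edgeR). HMOX1, GCLM, the unfolded protein response genes DNAJB9 and XBP1, and SESN2 rose (log2 2.09 ± 0.48, 2.30 ± 0.39, 1.52 ± 0.16, 0.95 ± 0.19 and 1.18 ± 0.12, adjusted p = 0.0047, 0.00054, 1.3e-05, 0.0018 and 9.2e-06 by edgeR). PPARG and the lipase LPL fell (log2 -2.25 ± 0.22 and -3.61 ± 0.75, adjusted p = 7.1e-06 and 0.0026 by edgeR). ACOD1 and ANKRD22 fell (log2 -3.76 ± 0.84 and -4.24 ± 0.68, adjusted p = 0.0042 and 0.00037 by edgeR). The interferon-inducible MNDA, VCAN and the inhibitory receptor LILRB4 fell (log2 -2.23 ± 0.36, -2.12 ± 0.42 and -1.93 ± 0.36, adjusted p = 0.00045, 0.0019 and 0.0012 by edgeR). The transglutaminase TGM2 and the actin-binding SYNPO2 fell (log2 -3.47 ± 0.54 and -6.05 ± 1.29, adjusted p = 0.00029 and 0.0030 by edgeR). For genes named here and past the threshold, folds that moved by more than 1.5 times without 1 library included those below, on the log2 scale. They were ANKRD22 -4.88 and ACOD1 -4.62 without NSA+GSK872+CXCL4+ORN8L replicate 3. Without CXCL4+ORN8L replicate 1 they were TNFSF15 -2.60 and LPL -2.98. Without NSA+GSK872+CXCL4+ORN8L replicate 1 they were TNFSF15 -4.43 and SYNPO2 -7.31. Without NSA+GSK872+CXCL4+ORN8L replicate 4 that of HMOX1 was 1.49. Without CXCL4+ORN8L replicate 4 they were NAIP -1.81 and ACOD1 -3.12.

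Camera moved up NRF2 genes and unfolded protein response genes. Camera's adjusted p-values in that order were 4.3e-06 and 0.0015, and the same test gave adjusted p = 0.58 and 0.79 with an estimated correlation. Of the unfolded protein response genes 7 of 20 rose (8 adjusted over the list alone). It moved down LXR genes, hypoxia genes and ribosomal protein genes. In that order, camera's adjusted p-values were 0.022, 0.022 and 0.022, and the same test gave adjusted p = 0.57, 0.58 and 0.95 with an estimated correlation. Of these lists 6 of 16, 11 of 28 and 7 of 33 members fell (6, 12 and 7 adjusted over the list alone), and 1, 1 and 0 rose (1, 3 and 0 adjusted over the list alone). Members that rose and that fell with the replicate block were 4 and 7 of the 24 inflammasome genes, 15 and 1 of the 21 NRF2 genes, 5 and 14 of the 28 hypoxia genes and 0 and 15 of the 33 ribosomal protein genes. Of the dendritic cell markers 3 of 11 fell (3 adjusted over the list alone, 6 with the block; median log2 -0.93, camera adjusted p = 0.13, fry adjusted p = 0.00088), and of the neutrophil markers 1 of 7 fell (1 adjusted over the list alone; median log2 -0.80, camera adjusted p = 0.39, fry adjusted p = 0.029). Macrophage identity genes moved down with the replicate block alone (adjusted p = 0.018 by camera, 0.42 with an estimated correlation). Other splits of the 8 libraries moved up to 15 lists, and with only the libraries whose labels name 1 group the edgeR count was 1645. SYNPO2 and IL6 changed by -3.82 and 2.96 on the log2 scale without CXCL4+ORN8L replicate 1. By edgeR, IL6 ended without any 1 of 6 libraries, all but CXCL4+ORN8L replicate 1 and NSA+GSK872+CXCL4+ORN8L replicate 2 (adjusted p up to 0.14). GSDMD ended without CXCL4+ORN8L replicate 3 or 4 or NSA+GSK872+CXCL4+ORN8L replicate 1, 2 or 4 (edgeR adjusted p up to 0.12). MLKL ended without CXCL4+ORN8L replicate 1 or 3 or NSA+GSK872+CXCL4+ORN8L replicate 2 (edgeR adjusted p up to 0.081). CXCL5 ended without NSA+GSK872+CXCL4+ORN8L replicate 2 (edgeR adjusted p = 0.053). IL1B and NLRP3 passed without CXCL4+ORN8L replicate 1 (log2 1.51 and 1.35, edgeR adjusted p = 0.026 and 0.017). That fit keeps NSA+GSK872+CXCL4+ORN8L replicate 1 of the same donor. Within pairs NLRP3 was lower with both inhibitors in replicate 1 (428 against 731 CPM) and higher in replicates 2, 3 and 4. CXCL10 and TLR8 passed without NSA+GSK872+CXCL4+ORN8L replicate 3 (log2 -1.92 and -1.91, edgeR adjusted p = 0.025 and 0.018).

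The last comparison asked whether the genes moved by GSK872 on top of NSA were genes the stimulus moves; the libraries of these comparisons do not overlap. Of the 1348 genes lowered with GSK872, 650 had risen with the stimulus, against 435 for independent lists, and 280 had fallen, against 436. Of the 1199 genes raised with GSK872, 405 had risen with the stimulus, against 387, and 437 had fallen, against 388. Fisher's exact test, taken across genes, which are not independent replicates, gave p = 1.1e-37, 4.2e-23, 0.24 and 0.0017 in that order. The numbers for independent lists take no account of a gene's level, on which a call depends. The part of level in these overlaps was not tested. Among the genes lowered with GSK872, TNFSF15, P2RX7 and CASP1 stood higher with the stimulus and IRAK1 lower, in every same-numbered pair. Among those raised, IL12B and CXCL10 stood higher with the stimulus and CD86 lower, in every same-numbered pair. With the replicate block the 4 overlaps were 1156, 567, 800 and 976, against 817, 856, 831 and 871 for independent lists, so the third lay below that number with the block and above it without (Fisher's exact p = 0.14 with the block).

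The genes central to the question lie as follows on GRCh38 by GENCODE 29 and all are protein-coding: RIPK3 (ENSG00000129465.15, chromosome 14, 24336021 to 24340045), MLKL (ENSG00000168404.12, chromosome 16, 74671855 to 74700960), NLRP3 (ENSG00000162711.17, chromosome 1, 247416156 to 247449108) and CASP1 (ENSG00000137752.23, chromosome 11, 105025443 to 105035250). For genes of the interferon and stress responses the positions were CXCL10 (ENSG00000169245.5, chromosome 4, 76021117 to 76023497), IL12B (ENSG00000113302.4, chromosome 5, 159314783 to 159330887), TLR8 (ENSG00000101916.11, chromosome X, 12906620 to 12923169) and HMOX1 (ENSG00000100292.16, chromosome 22, 35380361 to 35394214).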

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

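No test in this part was chosen after its result was seen. Among 252 groups of 4 libraries (the levels of the named genes and 4 measures of library quality), 28 had 1 library so far from the nearest other that the gap, as a share of the group's range, was above the 95% critical value of Dixon's test. That is 11.11% of the groups. Chance gives about 5% only for normally distributed and independent values, which CPM of genes from the same libraries need not be. The cytokine gene TNF was alone in having a library above that critical value in all 4 groups.

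In unstimulated cells, replicate 2 was high for 7 genes that the stimulus raises: ACOD1 (1.45 CPM, the other 3 libraries 0.146 to 0.284), IDO1 (2.23 CPM, the other 3 libraries 0.356 to 0.572), IL1B (74.95 CPM, the other 3 libraries 27.4 to 31.9), IL6 (5.39 CPM, the other 3 libraries 2.03 to 2.55), LAMP3 (2.23 CPM, the other 3 libraries 0.146 to 0.440), TNF (70.1 CPM, the other 3 libraries 27.8 to 29.5) and TNIP3 (6.05 CPM, the other 3 libraries 1.23 to 1.67). The number of genes with a count was low in unstimulated replicate 3, at 19010 against 20562 to 20882 in the other 3 libraries.

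With CXCL4+ORN8L, replicate 1 was high for 5 genes: IFNB1 (13.3 CPM, the other 3 libraries 0.632 to 1.28), ISG15 (1571 CPM, the other 3 libraries 878 to 988), SYNPO2 (504 CPM, the other 3 libraries 16.6 to 57.3), TNF (46280.2 CPM, the other 3 libraries 2323 to 9746) and TNFRSF11A (3.09 CPM, the other 3 libraries 2.02 to 2.14). CXCL4+ORN8L replicate 4 was high for the death ligand gene TNFSF10 (534 CPM, the other 3 libraries 254 to 286).

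With NSA+CXCL4+ORN8L, replicate 3 was high for ANKRD22 (233 CPM, the other 3 libraries 34.7 to 65.5), CASP8 (16.9 CPM, the other 3 libraries 14.6 to 14.9), CXCL10 (119 CPM, the other 3 libraries 34.0 to 45.8), HAS1 (35.4 CPM, the other 3 libraries 6.17 to 9.78) and MAF (13.4 CPM, the other 3 libraries 3.32 to 4.63), and low for the chaperone gene DNAJB4 (130.1 CPM, the other 3 libraries 169.6 to 177). Replicate 1 of this group was high for IL6 (2129 CPM, the other 3 libraries 866 to 1014) and TNF (29588 CPM, the other 3 libraries 12329 to 13453). Replicate 4 was low for BIRC3 (179.7 CPM, the other 3 libraries 270.0 to 273), an inhibitor of apoptosis. Replicate 2 had the lowest total count, 14077215 against 15942179 to 16236916.

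With NSA+GSK872+CXCL4+ORN8L, replicate 1 was high for SYNPO2 (6.07 CPM, the other 3 libraries 0.580 to 1.47) and TNF (17600.1 CPM, the other 3 libraries 4542 to 6724), and replicate 3 for ACOD1 (117 CPM, the other 3 libraries 24.9 to 29.3) and CEBPD (649 CPM, the other 3 libraries 241 to 280.0). No explanation of these single values was tested.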

How the results depend on the processing

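The fit without CXCL4+ORN8L replicate 1 and NSA+CXCL4+ORN8L replicate 3, which stand apart from their groups, was chosen after the data were seen, and the cause of each change below was not tested unless stated. Counts of genes follow the order stimulus (8804), NSA (2571), GSK872 on top of NSA (2547) and both inhibitors (3807). RLE normalization, DESeq2, limma-voom and a filter of at least 1 CPM in 8 libraries each left the 4 counts within 1.5 times these, and RLE moved the median of all genes by at most 0.04 on the log2 scale. Of 164 changes of single genes, no filter ended the call of 22 (adjusted p up to 0.18), among them IL18 with the stimulus, TRIB3, IL12B and TNFSF10 with NSA, CXCL10, CXCL11, CXCL5, BIRC3, TBK1, P2RX7, IL18BP, LPL, HMOX1, DUSP6 and ANKRD22 with GSK872, EREG, CXCL5, IL6, LAMP3 and GSDMD with both inhibitors. Only the 2 groups compared ended 6, among them TRIB3 and TNFSF10 with NSA, CXCL11 with GSK872, IL6 and MLKL with both inhibitors, and gained 2 (MX1 with NSA, IL6 with GSK872). The limma-voom fit ended 4, among them IL18 with the stimulus, CXCL11 and LPL with GSK872. RLE ended 1 (IL6 with both inhibitors), and the filter of 1 CPM ended 1 (IL18 with the stimulus). DESeq2 gained 7 (MLKL, CASP8, IFNB1 and IFIT1 with NSA, IL6 and TLR8 with GSK872, TLR8 with both inhibitors). Only the libraries with labels alike ended 54 and gained 1, and the groups of the treatment field ended 93. The replicate block gave 4398 for NSA and 4669 for GSK872, and overlaps of 800 (both rose), 1156 (stimulus rose, GSK872 fell), 976 (stimulus fell, GSK872 rose) and 567 (both fell). It turned IL6 with NSA to 0.33 and changed no other call than those printed beside their results. Only the 2 groups compared gave 1111 for NSA. No filter gave 1664 for GSK872, overlaps of 369, 281 and 162 (in the order above, the first within 1.5 times), and 15 and 10 lists moved for GSK872 and both inhibitors. Only the 8 libraries with labels alike, 2 per group, gave 293, 487 and 1645 genes for NSA, GSK872 and both inhibitors, and overlaps of 52, 166, 31 and 67. This setting, which has fewer libraries, reversed MLKL (-0.084) with the stimulus, IL6 (1.10) with NSA, and IFIT1 (0.076), ISG15 (0.30) and TNF (0.62) with both inhibitors. Without the 2 libraries that stand apart, which leaves different donors in the 2 groups, NSA gave 4070. The limma-voom fit reversed IL6 with NSA (0.38) and IFNB1 with GSK872 (-0.62). Fry moved 26 lists with the stimulus and 8 with both inhibitors. It asks whether a list's genes move, not whether they move more than others. An estimated correlation moved 0 lists in all 4 comparisons by camera, with 8, 7, 2 and 2 under an unadjusted p of 0.05, where fry moved 26, 15, 9 and 8. With the groups of the treatment field edgeR changed 0 genes in all 4. At an unadjusted p under 0.05 it changed 1473, 220, 1815 and 2462. At an adjusted p under 0.05 DESeq2 changed 31, 0, 76 and 304 and limma-voom 0 in all 4. That setting mixes the groups of the titles. With the stimulus it reversed TNF (-0.16), IL6 (-0.092), IL12B (-0.59), INHBA (-0.015) and IFNB1 (-2.41). With NSA it reversed TRIB3 (-0.15), IL12B (0.69), HTRA3 (-0.88), TNF (-0.065), IL6 (1.52) and ISG15 (0.092). With GSK872 it reversed CXCL5 (-1.46), BIRC3 (-0.48), TBK1 (-0.44), GSDMD (-0.13), IL18BP (0.71), IRAK1 (0.55), PPARG (0.97), LPL (0.66), SQLE (1.98), MSMO1 (0.45), HSPB1 (0.69), HAVCR2 (1.27), DUSP6 (0.68), IL6 (-0.45), IL1B (-0.97), IFNB1 (-0.020), IFIT1 (-0.18), ISG15 (-0.28), MX1 (-0.60), IL18 (-0.32), MLKL (-0.44), CASP8 (0.86) and IRF5 (1.06). With both inhibitors it reversed GCLM (-1.10), HMOX1 (-1.55), DNAJB9 (-0.020), XBP1 (-0.091), NAIP (0.43), TLR7 (0.64), STING1 (2.22), VCAN (0.39), IL1B (-0.37), NLRP3 (-0.28), RIPK3 (0.24), IRF5 (0.11) and TBK1 (-0.16). Leaving out each library or replicate number in turn gave 515 to 3467 genes for NSA, 1074 to 2968 for GSK872 and 2292 to 3665 for both inhibitors. It gave 3 to 9 lists for the last and overlaps of 146 to 247, 258 to 432, 127 to 250 and 124 to 177 in the order above. The lowest came without replicate 4 for NSA (765 without replicate 2) and both inhibitors (2326 without replicate 2), and without replicate 2 for GSK872 (1220, 1474 and 1439 without replicates 1, 3 and 4). Among the fold changes that reversed, MLKL ranged from -0.038 to 0.38 with the stimulus. With NSA the ranges were TNF -0.35 to 1.49, IL6 -0.45 to 1.10 and IL18 -0.11 to 0.45. With GSK872 they were IFNB1 -0.050 to 1.35, NLRP3 -0.27 to 0.094, IL18 -0.064 to 0.55, MLKL -0.032 to 0.29 and CASP8 -0.12 to 0.0037. With both inhibitors they were IFIT1 -0.42 to 0.019, ISG15 -0.35 to 0.12, TNF -1.53 to 0.53 and NLRP3 -0.044 to 1.35. None of these genes was past the threshold in that comparison with all libraries. The difference in mitochondrial share with NSA ranged from -0.180 to 0.511 percentage points, and that in genes with a count from -185 to 1015 with NSA and from -352 to 615.0 with both inhibitors. Lists that camera no longer moved, or that fry in its place did not move, were the integrated stress response with the stimulus (RLE 0.054, without replicate 1 0.077, without replicate 2 0.092), macrophage identity (without replicate 2 0.051) and oxidative phosphorylation (without replicate 4 0.059). With NSA they were the brakes (without replicates 1 and 2 0.18 and 0.059), the integrated stress response (without replicate 3 0.13), antigen presentation (fry 0.077, without replicate 1 0.18) and dendritic cell markers (without replicate 2 0.054). With GSK872 they were interferon-stimulated genes (fry 0.11) and NRF2 genes (fry 0.089, without replicate 2 0.0502). With both inhibitors they were hypoxia genes (without replicate 1 0.098) and ribosomal proteins (fry 0.14, without replicate 1 0.10). In simulated counts, changes of 1.5-fold were mostly missed by the fit without the block.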

Other observations

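The tests on markers of other blood cells and on exchanged libraries were chosen after the result was seen; for the test of the labels, the lack of calls with the groups of the treatment field was known before, the distances to the groups were not. CXCL4+ORN8L also moved genes of lists that did not pass camera. Of the LXR and lipid efflux genes 2 rose and 10 fell of 16 (2 and 10 adjusted over the list alone, camera adjusted p = 0.081). Of the cholesterol synthesis and uptake genes 4 rose and 8 fell of 22 (4 and 8 adjusted over the list alone, camera adjusted p = 0.20). Of the monocyte identity genes 5 rose and 10 fell of 25 (5 and 10 adjusted over the list alone, camera adjusted p = 0.080). Of the antigen presentation and costimulation genes 6 rose and 4 fell of 20 (6 and 4 adjusted over the list alone, camera adjusted p = 0.21). Of the TLR8 and IRF signalling genes 13 rose and 6 fell of 27 (14 and 6 adjusted over the list alone, camera adjusted p = 0.21). Hypoxia and glycolysis genes went both ways, and 15 rose and 9 fell of 28 (16 and 9 adjusted over the list alone, camera adjusted p = 0.091). Of the p53 target genes 5 rose and 11 fell of 18 (5 and 11 adjusted over the list alone, camera adjusted p = 0.35). Of the cell cycle genes 1 rose and 8 fell of 18 (1 and 7 adjusted over the list alone, camera adjusted p = 0.16). Of the NRF2 genes 11 rose and 5 fell of 21 (11 and 5 adjusted over the list alone, camera adjusted p = 0.47). Of the heat shock genes 10 rose and 3 fell of 20 (10 and 3 adjusted over the list alone, camera adjusted p = 0.23). Of the metallothioneins 4 rose and 1 fell of 11 (4 and 1 adjusted over the list alone, camera adjusted p = 0.23).

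Markers of other cell types were measured in low numbers. With the stimulus, of the T cell markers 2 rose and 1 fell of 9 (2 and 1 adjusted over the list alone, camera adjusted p = 0.92), and of the B cell markers 2 rose and 2 fell of 8 (2 and 2 adjusted over the list alone, camera adjusted p = 0.98). Of the neutrophil markers 1 rose and 3 fell of 7 (1 and 3 adjusted over the list alone, camera adjusted p = 0.92), of the platelet markers 3 rose and 1 fell of 7 (3 and 1 adjusted over the list alone, camera adjusted p = 0.63) and of the dendritic cell markers 4 rose and 3 fell of 11 (4 and 3 adjusted over the list alone, camera adjusted p = 0.96). Of the 8 NK cell markers 3 rose (3 adjusted over the list alone, camera adjusted p = 0.60, fry adjusted p = 0.015). Of the nuclear-retained transcripts, a sign of RNA quality, 5 rose and 2 fell of 8 (5 and 2 adjusted over the list alone, camera adjusted p = 0.60, fry adjusted p = 0.028). Of the ribosomal protein genes 4 of 33 rose by edgeR over all genes and 0 adjusted over the list alone, where 4 were higher at an unadjusted p under 0.05, 4 by DESeq2 and 4 by limma-voom. Of the mitochondrial transcripts the same counts were 1 of 15, 0, 2, 3 and 2. These rises are on the TMM scale, while the mitochondrial share of all counts was lower with the stimulus in 4 of 4 pairs. Members that rose and that fell with the stimulus in the blocked fit were 5 and 4 of the 11 metallothioneins, 3 and 3 of the 8 B cell markers, 4 and 1 of the 8 NK cell markers, 2 and 4 of the 7 neutrophil markers and 3 and 0 of the 15 mitochondrial transcripts.

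Other splits of the 8 libraries of each comparison into 4 and 4, 35 in all, test whether chance alone gives as many calls. With the stimulus 1 of 35 splits, the real one, gave as many genes as 8804 by edgeR, and the highest of the others was 0 (3957 at an unadjusted p under 0.05, against 9258). For GSK872 it was 1 of 35 (2547, highest other 2) and for both inhibitors 1 of 35 (3807, highest other 32). This would exclude chance for these 3 only if the 8 libraries could be exchanged freely, which their pairing by donor goes against. For NSA 2 of 35 gave as many (2571, highest other 2668), so this count does not exclude chance. The other split exchanges CXCL4+ORN8L replicate 1 and NSA+CXCL4+ORN8L replicate 3, the libraries that stand apart from their groups. It keeps the rest in their groups, so it is not free of the NSA contrast. The only further split with calls for NSA, of donors 1 and 2 against donors 3 and 4, changed 991 genes. The splits that keep the pairing by donor, which part all 4 same-numbered pairs, are 8, too few for a share under 0.05. Among them the highest other was 0 by edgeR in each comparison (2535, 1459, 900 and 1370 at an unadjusted p under 0.05, against 9258, 4519, 4630 and 5399 for the real ones), and the others put libraries of the same treatment on both sides. The numbers of lists that camera moved, 13, 12, 7 and 5, were reached in 14, 9, 25 and 29 of 35 splits (highest others 18, 17, 16 and 15), so chance is not excluded for them. The 650 genes that rose with the stimulus and fell with GSK872 were reached in 1 of 35 splits (highest other 1), but the other splits changed at most 2 genes in all, so this says nothing on the excess of 650 over 435.

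The rise of NRF2, heat shock and unfolded protein response genes with NSA had a median of 0.78 over 61 measured members (quartiles 0.45 to 1.12 on the log2 scale). Without CXCL4+ORN8L replicate 1, the library of lowest depth, the median was 0.90, and after each library's trend on GC content and gene length was removed in the blocked fit it was 0.81, against 0.79 before. The trend itself gave the members -0.0554 to 0.0839, far below the rise, which argues against GC content and length as the cause, as the median without that library does against its low depth. The correction moved all genes by a median of 0.013 and the calls from 4398 to 4570, with 49 members past the threshold before and 50 after. Nuclear-retained transcripts, a sign of RNA quality, had a median of 0.61 with NSA. Of these 8, 0 passed edgeR's test, 2 rose with the block and 3 were higher at an unadjusted p under 0.05. The list's adjusted p was 0.18 by camera and 0.063 by fry. Mitochondrial transcripts and ribosomal protein genes had medians of 0.023 and -0.093. A part of RNA quality in the rise was not tested. Markers of 5 other blood cell types (T, B and NK cells, neutrophils and platelets) had a median of -0.18 over 39 genes (quartiles -0.82 to 0.15). By type, in that order, the medians were -0.12, 0.16, -0.67, -0.67 and -0.0087. This argues against a larger number of such cells as the source of a rise of 0.78. A stress response within such cells, at an unchanged number, would leave these markers as they are, so it was not tested. That NSA may itself set off a stress response stays a hypothesis found on these data, and a part of the vehicle stays open too. No group tests either, as NSA was not given without the stimulus.

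Some genes moved by NSA moved back with GSK872 on top, more than independent lists would give. Of the 1407 genes that fell, 291 then rose, against 124 for independent lists. Of the 1164 that rose, 217 then fell, against 115. With the block these overlaps were 763 against 404 and 666 against 350.4. Most genes moved by NSA were thus not called as moving back. The correlation of the fold changes was -0.38 and the covariance -0.229 across genes, which are not independent replicates, but both comparisons share the NSA libraries. Unchanged groups simulated with shared libraries gave a covariance of -0.0843 and a correlation of -0.51, so the covariance differs by -0.145 (-0.244, -0.0489 and -0.196 with the block). With separate pairs of NSA libraries the covariance was -0.228 to -0.100 in 6 of 6 assignments, with overlaps of 30 to 79 against 5.67 to 33.8 and 36 to 64 against 13.3 to 48.0, above the number for independent lists in 6 of 6 (180 to 265 against 58.3 to 119.8 and 195 to 226 against 75.7 to 129 with the block, in 6 of 6 too), so the shared libraries are not the whole cause. GSK872 may offset part of the response to NSA, CXCL10, IL12B and HMOX1 among it, which a group with GSK872 alone would test.

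Titles and treatment fields of 8 libraries name different groups. Against the means of the 8 libraries whose labels are alike, 8 of these 8 lay nearest to the group of the title and 0 to that of the treatment field (7 and 0 without centring on the replicate number). This argues against the explanation that the treatment fields are right and the titles wrong, and for the reverse, that the titles are right and the treatment fields wrong. An exchange of libraries of different donors between the stimulus group and the NSA group is argued against too, since 8 of 8 libraries of these groups deviated most like those of their own replicate number in the other groups. An exchange between groups within 1 donor that left both labels alike is argued against as well. Of the 16 libraries, 16 lay nearest to the mean of their own group over the other replicate numbers (14 without centring on the replicate number). The same exchange in all donors among the 3 stimulated groups would leave no trace in this test and stays open.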
